A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

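The study hybridised RNA from 8 adapted Saccharomyces cerevisiae mutants, each against a fluorescent reference strain, on 2-colour spotted arrays. There were 3 slides with 8 arrays each, 24 arrays in all, and per the labels a replicate number is a slide. The series description calls the 3 sets biological replicas, and the 8 arrays of a slide share that slide. PY-231 had the YFP reference, PR-438, PR-338, PR-164 and M1 had the DsRed reference, and PG-259, PG-353 and PG-132 had the GFP reference. The mutant was labelled with Cy5 on slides 1 and 3 and with Cy3 on slide 2. Each mutant held the same place on every slide, so place and mutant cannot be separated. Per the labels, 5 µg of cDNA was labelled, and the cultures were grown in YNB minimal medium without glucose and in hydrolysate at 1 g/mL. The labels do not say whether these were 1 medium or separate ones.

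The deposited table holds 15744 probes, in another unit than the usual normalised log ratio. Its values are linear ratios of the brightness of both channels after background subtraction, with no scaling of channels or arrays, and how the authors made them beyond GenePix result files is not given in the sources used here. This was read from the values, which are quotients of whole numbers (82.6% to 100% of an array's values could be written so with a denominator up to 10000) and are at or below 0 for 2.14% to 8.28% of an array's spots. Array medians ran from 0.22 to 1.41 on slides 1 and 3 and from 2.44 to 5.41 on slide 2. Spots at or below 0 were left out, ratios were put on the log2 scale and each array was centred on the median of its named probes, which moved single arrays by -2.19 to 2.46. All changes are relative to that median. Of the probes, 8152 carried 1 gene symbol and 7592 carried none and were not analysed here. The 4073 symbols were brought to current names in the gene catalogue of the R64 assembly (129 through a synonym, 4 unmatched), which gave 4069 genes tested, 4036 of them on all arrays, each as the mean of its probes. No filter on brightness was applied.

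The direction of the ratio on slide 2 is not stated. The rule fixed for it compared slide 2 with slides 1 and 3 within each mutant across genes, after the mean of a slide's 8 arrays was subtracted. Its median Pearson correlation over 8 mutants was 0.0265 and its Spearman counterpart -0.0255, too weak to settle the matter, though by the rule a Pearson median above 0 meant that slide 2 had been turned already. Values were therefore read as mutant over reference on every slide, which is likely since array medians lay above 1 on all of slide 2 and mostly below 1 on the others, and since the mating-type genes of M1 and chromosome VIII of PR-438 had the same direction on slides 2 and 3. The medians, the mating-type genes and the chromosome were brought in after they were seen. After the same subtraction slides 1 and 3, which share a dye orientation, correlated at a median of -0.052. Arrays of 1 mutant thus hardly resembled each other there. Before the subtraction slide 2 correlated with slides 1 and 3 at a median of -0.401, and slide 1 with slide 3 at 0.227. These 2 values hold dye effects shared by a slide, so they cannot settle the direction. The 45 pairs of arrays of different mutants with the same reference and dye orientation correlated at -0.174 to 0.928, with a median of 0.359, while the highest Spearman correlation was 0.419 between 2 arrays of 1 mutant and 0.798 between any 2 arrays.

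Signal over background stands in for depth here, and the number of arrays limits the precision. The correlation between the probes of 1 gene was 0.366 to 0.817 on 23 arrays and 0.011 on PY-231 replicate 1, which therefore carried no gene signal. It stayed in the fit, and results without it are given as an alternative.

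Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the data.table package, version 1.17.8. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. One fit over 24 arrays had a coefficient per mutant and a dye term (+1 with the mutant in Cy5, -1 in Cy3), tested each log2 ratio against 0, and called genes at a Benjamini-Hochberg adjusted p under 0.05. A ratio against 0 leaves out the spread of the reference cultures themselves. Slide 2 was the only slide with the mutant in Cy3, so the dye term also takes whatever its arrays share out of the residuals. The SE and p-values therefore do not measure the spread between slide 2 and the other slides. The fitted ratios still hold part of what slide 2 shares. In the mean of the 8 mutants slide 2 counts as much as slides 1 and 3 together. The mean of the 8 mutant coefficients was tested in the same fit, and moderated F tests compared the 4 mutants with the DsRed reference and the 3 mutants with the GFP reference. The median residual SD was 0.379 on the log2 scale. The fit was also tested on simulated data.

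There were 51 gene lists, each tested with at least 4 measured members by camera with a preset correlation of 0.01 in 9 contrasts (459 tests), beside camera with an estimated correlation and fry. Camera was run on genes with a value on every array. For chromosomes, each array's median over the genes of a chromosome minus the median over all genes was tested against 0 in 128 tests. The lists, designs, naming rule and most alternative settings were fixed before the data were examined. Named per mutant are the 6 highest and 6 lowest called genes with 1 sign on all 3 arrays, for the mean of 8 mutants the 12 highest and 12 lowest called genes with 1 sign in all 8 mutants, for the F tests the 10 genes with the smallest adjusted p, and for a list up to 4 members with the smallest p. Other genes that are named were chosen after their values were seen, which is said there.

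The alternative settings fixed then were no dye term, a replicate block, no centring, scaling to 1 spread, the median of a gene's probes, genes on all arrays, eBayes with trend and robust settings, arrays with the same reference only, arrayWeights, the opposite orientation of slide 2, and leaving out each replicate. Chosen after seeing the data were a loess of each array on probe brightness with span 0.3, leaving out the dimmest 25% of probes, leaving out single arrays, and 1 mean per slide. Brightness was recovered from the quotients, and the brightest probes share a ceiling, so the loess does not remove a trend among these.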

Results

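Gene expression was measured on 2-colour arrays in 8 Saccharomyces cerevisiae strains adapted to tolerate hydrolysates of lignocellulosic biomass, the sugar-rich but inhibitory liquor made from plant material. Each strain was compared with a reference strain named after its fluorescent protein. PY-231 was set against YFP, PR-438, PR-338, PR-164 and M1 against DsRed, and PG-259, PG-353 and PG-132 against GFP, with 3 arrays per strain and 24 arrays in all. Ratios are log2 of mutant over reference from limma, with the SE of the fit and n = 3 arrays unless stated. Their direction on slide 2 is likely but not stated in the labels, and with the opposite one 37 of the 58 named results turned sign. Of the 33 calls followed in single mutants, where a gene counts once per mutant, 7 also passed in the same direction without replicate 1. The number was 3 without replicate 2, 9 without replicate 3, 6 after a loess on brightness and 0 with that opposite direction. Most of these were picked for 1 sign on all 3 arrays, which a turned slide 2 makes cancel, so that 0 was close to fixed in advance. Between 15647 and 15737 spots per array had a value, and 4069 named genes were tested.

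M1 differed from its DsRed reference in the genes that mark yeast mating types. Of the a-cell-specific genes, MFA2, which encodes a-factor, rose by 4.45 ± 0.76 (adjusted p = 0.0147) and BAR1, the protease that degrades alpha-factor, rose by 2.77 ± 0.43 (adjusted p = 0.0076). STE2, the alpha-factor receptor, rose by 2.71 ± 0.51 (adjusted p = 0.0215), while STE3, the a-factor receptor of alpha cells, fell by 3.81 ± 0.74 (adjusted p = 0.031). STE2 and STE3 were named after their values were seen. The 6 a-cell genes measured on every array shifted up together with a median of 2.67 (adjusted p = 3.9e-11 by camera, adjusted p = 0.811 with an estimated correlation), and 3 of them passed over all genes and 6 adjusted over the list alone. The 4 alpha-cell genes shifted down with a median of -3.39 (adjusted p = 0.000201, and 0.811 as the adjusted p with an estimated correlation), with 1 passing over all genes and 4 adjusted over the list alone. MF(ALPHA)1, which encodes alpha-factor, had -4.03 ± 0.98 and an adjusted p of 0.0807. The other alpha-cell genes, SAG1 and MF(ALPHA)2, were not low in M1 alone. SAG1 had -0.67 in M1, and -0.80, -0.60 and -0.89 in PR-438, PR-338 and PR-164. MF(ALPHA)2 had -2.98 in M1, and -2.03, -1.64 and -1.83 in the same order. These values were picked after they were seen.

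The differences in M1 stood on replicates 2 and 3 alone. MFA2 had 0.07 on replicate 1, 6.76 on replicate 2 and 6.26 on replicate 3, and STE3 had 0.56, -6.13 and -5.71. Without M1 replicate 1, a choice made after seeing the data, 16 genes were called in M1 in place of 10.

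**Figure D1:**
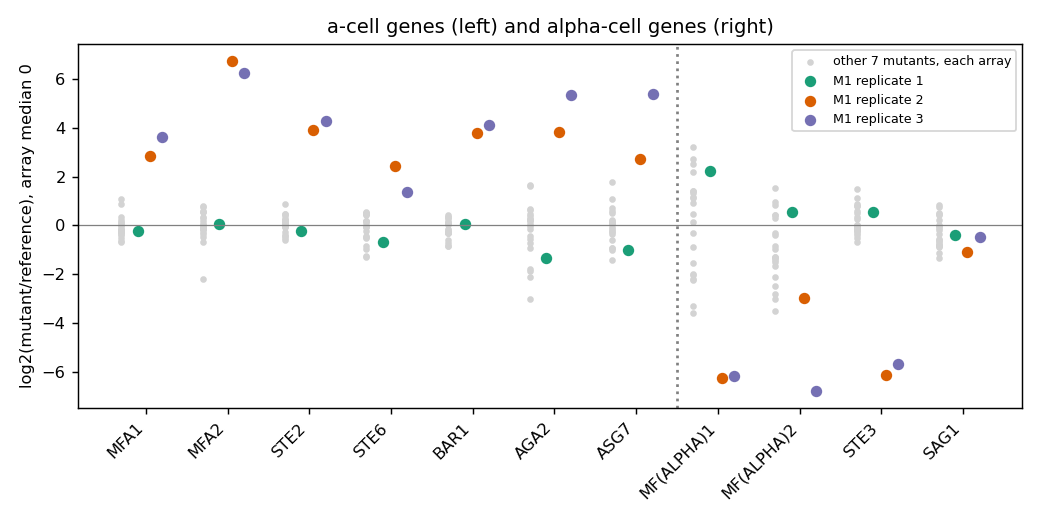
Log2 ratio of mutant over reference (y axis, array median at 0) for 7 a-cell genes and 4 alpha-cell genes (x axis), with coloured points for the 3 M1 arrays and grey points for each array of the other 7 mutants. MFA2 lies at 6.76 and 6.26 on M1 replicates 2 and 3 and at 0.07 on replicate 1.

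Beyond the mating genes, YPT32, a Rab-family GTPase of the secretory pathway, rose in M1 by 0.69 ± 0.14 (adjusted p = 0.0485). TIR1, a cell wall mannoprotein, fell by 2.20 ± 0.40, FAS2, the alpha subunit of fatty acid synthase, fell by 1.57 ± 0.27, PAB1, the poly(A)-binding protein, fell by 1.56 ± 0.24 and FKS1, a glucan synthase of the cell wall, fell by 1.23 ± 0.22. Each of these falls was largest on replicate 2, as for FKS1 at -0.25, -2.03 and -0.50 on replicates 1, 2 and 3. The 62 ribosome biogenesis genes shifted up with a median of 0.28, 57 of them above 0 (adjusted p = 3.56e-07, and adjusted p = 0.813 with an estimated correlation). Trehalose and glycogen genes shifted down with a median of -0.52 over 17 genes (adjusted p = 0.000464, and adjusted p = 0.811 with an estimated correlation). Among these GSY2, a glycogen synthase, had -1.36 ± 0.44 and PGM2, a phosphoglucomutase, had -1.37 ± 0.48, and neither passed over all genes, while 4 members passed adjusted over the list alone. The means of the ribosome biogenesis list and of this one did not differ among the 4 mutants with the DsRed reference. By moderated F test the adjusted p was 0.76 for each. In all, 4 genes rose and 6 fell in M1 (301 and 171 with the opposite orientation of slide 2), and 43 genes were called with a replicate block. After a loess on brightness 3 genes were called, BAR1, MFA2 and STE2, none of which passed without replicate 2 (adjusted p = 0.109, 0.129 and 0.159) or without replicate 3 (adjusted p = 0.163, 0.228 and 0.278).

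PR-338 and PR-164 had low values of AAD3 and RDS1, neighbours on chromosome III (R64 assembly, 313890 to 314981 for AAD3 and 310958 to 313456 for RDS1). AAD3, a putative aryl-alcohol dehydrogenase, fell by 2.45 ± 0.33 in PR-338 (adjusted p = 0.00245) and fell by 1.57 ± 0.33 in PR-164 (adjusted p = 0.0372). RDS1, a zinc cluster transcription factor, fell by 1.82 ± 0.32 in PR-338 (adjusted p = 0.0307) and fell by 1.65 ± 0.32 in PR-164 (adjusted p = 0.0295). In PR-438 and M1, which had the same reference, AAD3 was at -0.17 ± 0.33 and -0.16 ± 0.33. In PR-338, YCK2, a casein kinase I of the plasma membrane, rose by 1.21 ± 0.24, SBP1, an RNA-binding protein, fell by 1.42 ± 0.27 and PAB1 fell by 1.23 ± 0.24. In PR-164, TIR1 fell by 1.99 ± 0.40, PAB1 fell by 1.65 ± 0.24, LYS1 of lysine synthesis fell by 1.49 ± 0.31 and GUA1, the GMP synthase, fell by 1.48 ± 0.32. These genes in PR-164, and SBP1 and PAB1 in PR-338, were lowest on replicate 2. YCK2 in PR-338 was at 2.265, 0.111 and 1.475 on replicates 1, 2 and 3. It passed without replicate 2 (adjusted p = 0.0223), but not without replicate 1 or 3 (adjusted p = 0.367 and 0.401). Nor did YCK2 pass after the loess on brightness (adjusted p = 0.0663). SMA2, a gene of spore membrane assembly, was 1.97 ± 0.37 on 2 arrays and is named after its value was seen.

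Cytosolic ribosomal protein genes shifted down in both, with a median of -1.05 in PR-338 (adjusted p = 1.9e-43) and -1.10 in PR-164 (adjusted p = 4.4e-35) over 135 genes, and adjusted p = 0.811 with an estimated correlation in each. After a loess on brightness the medians were -0.34 and -0.50. The mean of the list did not differ among the 4 mutants with the DsRed reference (adjusted p = 0.995 by moderated F test). A shift that these 4 share cannot be told apart from a trait of that reference. In PR-164, RPL2B had -1.57 ± 0.32 and RPS24B had -1.64 ± 0.35 among 3 members that passed over all genes, and 61 passed adjusted over the list alone. In PR-338 none passed over all genes by limma, with 44 adjusted over the list alone, and 436 genes of the 4069 had an unadjusted p under 0.05. Genes of gluconeogenesis and the glyoxylate cycle shifted up in PR-164, with a median of 0.35 over 20 genes (adjusted p = 0.00101, and adjusted p = 0.811 with an estimated correlation). Among them FBP1, fructose-1,6-bisphosphatase, had 1.15 ± 0.41, but no member passed over all genes. PR-338 had 1 gene higher and 4 lower, PR-164 had 1 higher and 19 lower (204 and 85 with the opposite orientation of slide 2), and with a replicate block 8 and 34 genes were called. After the loess on brightness AAD3 and RDS1 still passed in PR-338 (adjusted p = 0.00114 and 0.0212). In PR-164 limma then called 0 genes, with 318 at an unadjusted p under 0.05. There AAD3 and RDS1 were at -1.641 and -1.698 after the loess (adjusted p = 0.0666 and 0.051), against -1.57 and -1.65 in the main fit. Without replicate 3, AAD3 and RDS1 did not pass in PR-338 (adjusted p = 0.22 and 0.307), and with the opposite orientation of slide 2 these were at -1.160 and -0.444 there (adjusted p = 0.483 and 0.816).

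In PR-438 the genes of chromosome VIII stood above the rest of the genome. Their median over 187 genes was 0.31 ± 0.07 above that of all genes (adjusted p = 0.025), with 0.01, 0.44 and 0.46 on replicates 1, 2 and 3. This was the 1 shift called among 128 tests of 16 chromosomes in 8 mutants, of which 22 had an unadjusted p under 0.05. The array labelled PG-259 replicate 1 had 0.42 for the same chromosome, against 0.03 and 0.08 on PG-259 replicates 2 and 3. The adjusted p in PR-438 was 0.0363 with a replicate block, 0.0626 after the loess on brightness, 0.0623 with the chromosome mean and 1.72e-08 without replicate 1. It was 0.172 without replicate 2, 0.446 without replicate 3 and 0.0529 with arrays of the same reference only, and with the opposite orientation of slide 2 the shift was -0.008 (adjusted p = 0.975). Among the 4 mutants with the DsRed reference the chromosome had an adjusted p of 0.0543 for a difference.

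**Figure D2:**
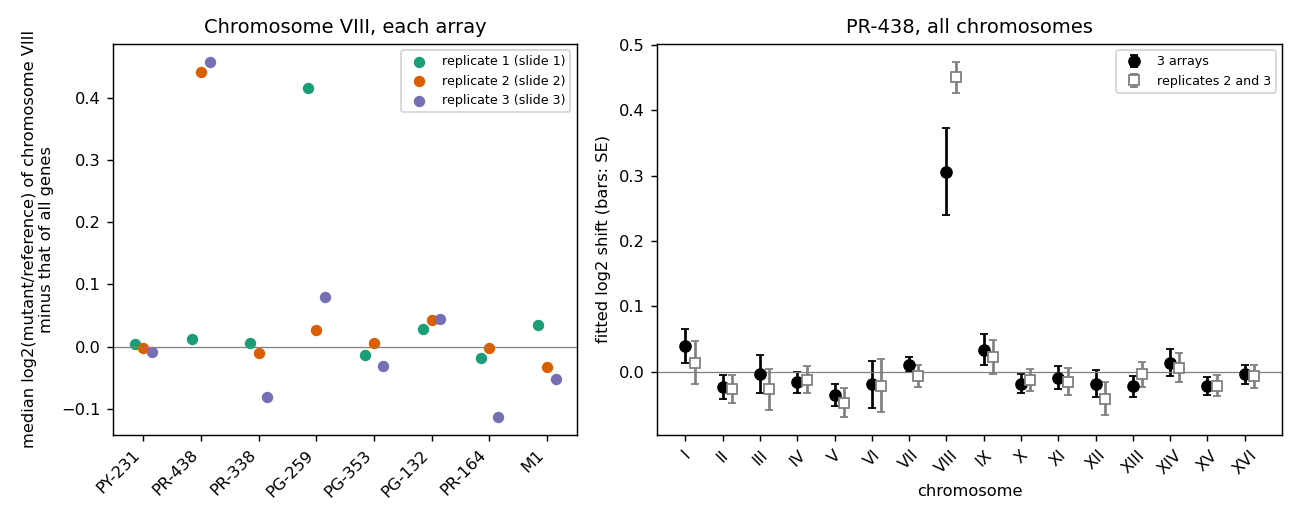
Left, median log2 ratio of chromosome VIII minus that of all genes (y axis) on each of 24 arrays by mutant (x axis), coloured by replicate. Right, the fitted shift of each chromosome in PR-438 (log2, bars are SE) with 3 arrays and with replicates 2 and 3, where chromosome VIII is at 0.31 and 0.45.

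The 12 genes called in PR-438 were all lower, while with the opposite orientation of slide 2 there were 57 higher and 1 lower. ARG1 of arginine synthesis fell by 1.75 ± 0.31, GUA1 fell by 1.63 ± 0.32, TKL1, the transketolase, fell by 1.5 ± 0.25 and PAB1 fell by 1.40 ± 0.24. The ribosomal protein genes RPL13A and RPS10B fell by 1.58 ± 0.32 and fell by 1.39 ± 0.28. Each of these falls was largest on replicate 2, as for TKL1 at -0.26, -2.59 and -0.64 on replicates 1, 2 and 3. Cytosolic ribosomal protein genes shifted down with a median of -0.92 (adjusted p = 4.9e-29), with 4 of 135 passing over all genes and 49 adjusted over the list alone, and ribosome biogenesis genes with a median of -0.38 over 62 genes (adjusted p = 5.61e-07). With an estimated correlation the adjusted p was 0.811 and 0.817. After the loess on brightness the medians were -0.14 and -0.36. Within ribosome biogenesis, CBF5, a pseudouridine synthase, had -0.94 ± 0.30, and no member passed over all genes or adjusted over the list alone. Trehalose and glycogen genes shifted up, with a median of 0.31 over 17 genes (adjusted p = 0.0126, and adjusted p = 0.813 with an estimated correlation). Among them GDB1, the glycogen debranching enzyme, had 1.37 ± 0.48, but no member of this list passed over all genes. Without replicate 1 this list did not pass (adjusted p = 0.368), and after the loess its median was 0.49. The mean of none of these lists differed among the 4 mutants with the DsRed reference. By moderated F test the adjusted p was 0.995 for cytosolic ribosomal proteins and 0.76 for each of the others. With a replicate block 20 genes were called, and after the loess on brightness limma called 0, with 407 at an unadjusted p under 0.05.

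Sulfate assimilation and methionine genes were low as a group in the 3 mutants with the GFP reference, and also in 2 others. Their median over 25 genes was -0.91 in PG-259 (adjusted p = 3.95e-09), -0.83 in PG-353 (adjusted p = 8.63e-11) and -0.91 in PG-132 (adjusted p = 9.55e-06). With an estimated correlation the adjusted p was 0.811, 0.811 and 0.813. In PY-231 the median was -0.37 (adjusted p = 0.0138, and adjusted p = 0.838 with an estimated correlation) and in PR-438 it was -0.34 (adjusted p = 0.0413, and adjusted p = 0.849 with an estimated correlation), and neither passed after the loess on brightness (adjusted p = 0.184 and 0.674) or without replicate 1 (adjusted p = 0.0743 and 0.288). In the mean of the 8 mutants it was -0.42 (adjusted p = 2.04e-05, and adjusted p = 0.813 with an estimated correlation), where SAM1, an S-adenosylmethionine synthetase, fell by 0.95 ± 0.16 and CYS4, cystathionine beta-synthase, fell by 0.59 ± 0.12. Across the GFP mutants MET10, a sulfite reductase subunit, had -1.01 ± 0.37, -0.90 ± 0.37 and -1.39 ± 0.37, and it was the 1 member that passed adjusted over the list alone, in PG-132. In these 3 the direction was the same after the loess on brightness, with a median of -0.49, -0.61 and -0.41 and an adjusted p of 3.34e-07, 8.91e-09 and 0.000982. The mean of the list did not differ among these 3 (adjusted p = 0.999 by moderated F test). Since these mutants share 1 reference, a shift in all 3, here or in the lists that follow, cannot be told apart from a trait of that reference.

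In the same 3 mutants general stress genes were low as well, with a median of -0.62 in PG-259, -0.54 in PG-353 and -0.70 in PG-132 over 19 genes (adjusted p = 0.000247, 0.000325 and 0.000794; adjusted p = 0.811, 0.811 and 0.813 with an estimated correlation). After the loess the medians were -0.38, -0.29 and -0.50. HSP12, a small heat shock protein, had -1.66 ± 0.63 in PG-132. Hypoxic genes, which are induced at low oxygen, had a median of -0.37, -0.43 and -0.37 over 16 genes in the same order (adjusted p = 0.00308, 0.000203 and 0.0144; adjusted p = 0.811, 0.811 and 0.812 with an estimated correlation), and in PG-132 they did not pass without replicate 1 (adjusted p = 0.0501). This list was down in PY-231 too (adjusted p = 0.035, and adjusted p = 0.813 with an estimated correlation), but did not pass after the loess (adjusted p = 0.0554). Mitochondrial ribosomal protein genes shifted up in PG-353, with a median of 0.20 and 49 of 57 above 0 (adjusted p = 1.53e-10, and adjusted p = 0.811 with an estimated correlation). This list passed with smaller medians in PY-231, PR-438, PG-259, PG-132 and PR-164 (adjusted p = 0.00191, 0.00361, 0.0163, 0.0282 and 0.000149; adjusted p = 0.83, 0.835, 0.849, 0.849 and 0.819 with an estimated correlation). The loess ended its call in PY-231 and PG-132 (adjusted p = 0.0815 and 0.15), and leaving out replicate 1 ended it in PG-259 and PG-132 (adjusted p = 0.943 and 0.365).

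Few single genes passed in these mutants. SPR1, an exo-glucanase of sporulating cells, fell by 1.32 ± 0.16 in PG-353 (chromosome XV, 690695 to 692032, adjusted p = 0.000402), at -0.85, -1.44 and -1.54 on its 3 arrays, and still passed after the loess on brightness (adjusted p = 0.00622). Without replicate 1, 2 or 3 it was at -1.486, -1.192 and -1.142 and did not pass (adjusted p = 0.0584, 0.32 and 0.17). It was at -0.227 with the opposite orientation of slide 2 (adjusted p = 0.832). FKS1 fell by 1.27 ± 0.22 in PG-259, where PAB1 at -1.38 ± 0.24 was the other called gene, named after its value was seen. In PG-132, PHB1, a prohibitin, fell by 1.28 ± 0.23, SMI1, a regulator of cell wall synthesis, fell by 1.18 ± 0.22 and ACC1, acetyl-CoA carboxylase, fell by 1.13 ± 0.23. These falls in PG-259 and PG-132 were largest on replicate 2. On replicates 1, 2 and 3 ACC1 had -0.27, -2.37 and -0.15 in PG-132, and FKS1 had -0.65, -2.16 and -0.095 in PG-259. PG-259 had 2, PG-353 had 1 and PG-132 had 9 genes called, all lower, and 3, 1 and 13 with a replicate block. With the opposite orientation of slide 2 there were 153 higher and 1 lower in PG-259 and 388 higher and 58 lower in PG-132. After the loess limma called 0 genes in PG-132, with 369 at an unadjusted p under 0.05, and in PG-259 INH1, an inhibitor of the mitochondrial ATP synthase, at 1.79 ± 0.27 (adjusted p = 0.0075). In the main fit INH1 was at 1.19 (adjusted p = 0.176). The loess moved it up as much as PAB1 (-1.383 to -0.784) and FKS1 (-1.274 to -0.674), as genes at the shared brightness ceiling. This call therefore cannot be told apart from that common move.

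In PY-231, iron regulon genes, which take up and distribute iron, were high as a group against the YFP reference. Their median was 0.47, with 23 of 24 above 0 (adjusted p = 4.75e-17 by camera, adjusted p = 0.262 with an estimated correlation, fry adjusted p = 0.0479). ARN2, a siderophore transporter, had 1.07 ± 0.27, CCC2, a copper transporter that supplies the iron oxidase, had 0.78 ± 0.26 and FET5, a multicopper oxidase, had 0.55 ± 0.14, and 7 members passed adjusted over the list alone. No single gene passed over all genes by limma, with 103 at an unadjusted p under 0.05 and a smallest adjusted p of 0.847. The list's shift was in the same direction after the loess on brightness (adjusted p = 2.99e-15) and without replicate 1 (adjusted p = 2.6e-22). PY-231 replicate 1, which carried no gene signal, is part of the fit behind these values. PY-231 was the only mutant with the YFP reference, so a change in the mutant cannot be told apart from a trait of that reference. The list was up in PG-353 and PG-132 too (adjusted p = 0.00796 and 0.0381; adjusted p = 0.813 with an estimated correlation in each), and in PG-132 it did not pass without replicate 1 (adjusted p = 0.0505).

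The mean of the 8 mutants asked what the adapted strains had in common. Low genes included cell wall proteins, with TIR1 at -1.42 ± 0.15 (adjusted p = 4.32e-06), UTR2, a chitin transglycosylase, at -1.30 ± 0.17 and SIM1 and UTH1 of the SUN family at -1.22 ± 0.16 and -1.12 ± 0.20. PAB1 fell by 1.28 ± 0.09 (adjusted p = 5.65e-08), LYS1 fell by 1.22 ± 0.12, FAS2 fell by 1.21 ± 0.10 and GUA1 fell by 1.20 ± 0.12. PAB1 was at -2.53 to -1.73 on the arrays of slide 2 and at -1.31 to 0.73 on the others. The dye term takes such a difference out of the residuals, so these SE and p-values do not measure it. The fitted mean is not freed of it, since slide 2 counts there as much as slides 1 and 3 together. RPO21, the largest subunit of RNA polymerase II, fell by 1.16 ± 0.18, GAR1, a protein of small nucleolar particles, fell by 1.16 ± 0.14, TUB1, alpha-tubulin, fell by 1.14 ± 0.16 and RVS167, an actin-associated protein of endocytosis, fell by 1.12 ± 0.19. Without replicate 2, where no dye term could be fitted, 11 of these 12 did not pass, and TUB1 and UTH1 turned to 0.118 and 0.107 (adjusted p = 0.692 and 0.79). With 1 mean per slide 2 of the 12 did not pass, but that fit keeps the dye term, so its p does not measure how slide 2 differs either. After the loess on brightness 3 did not pass, with values from -0.813 to -0.519. The loess moved all 12 by the same amount, as genes at the shared brightness ceiling, so it cannot test a trend with brightness among them.

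Of the genes that rose in the mean, MCH4, related to monocarboxylate permeases, rose by 0.42 ± 0.09 (adjusted p = 0.00235), SAP155, a partner of the Sit4 phosphatase, by 0.42 ± 0.08 and ARN1, a siderophore transporter, by 0.40 ± 0.11. PHR1, the DNA photolyase, rose by 0.35 ± 0.09, BPT1, a vacuolar ABC transporter, by 0.34 ± 0.09 and SIA1 by 0.30 ± 0.09. DAP2, a vacuolar peptidase, MBA1 and PNT1 of mitochondrial membrane insertion, LEU5, a mitochondrial carrier, SNO3 of pyridoxine metabolism and ATG3 of autophagy rose by 0.28 to 0.29. With 1 mean per slide, which counts the 8 arrays of a slide once, none of these 12 passed, and with the opposite orientation of slide 2 their values ran from -0.233 to 0.302 with 9 not passing. After the loess 5 of the 12 did not pass.

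**Figure D3:**
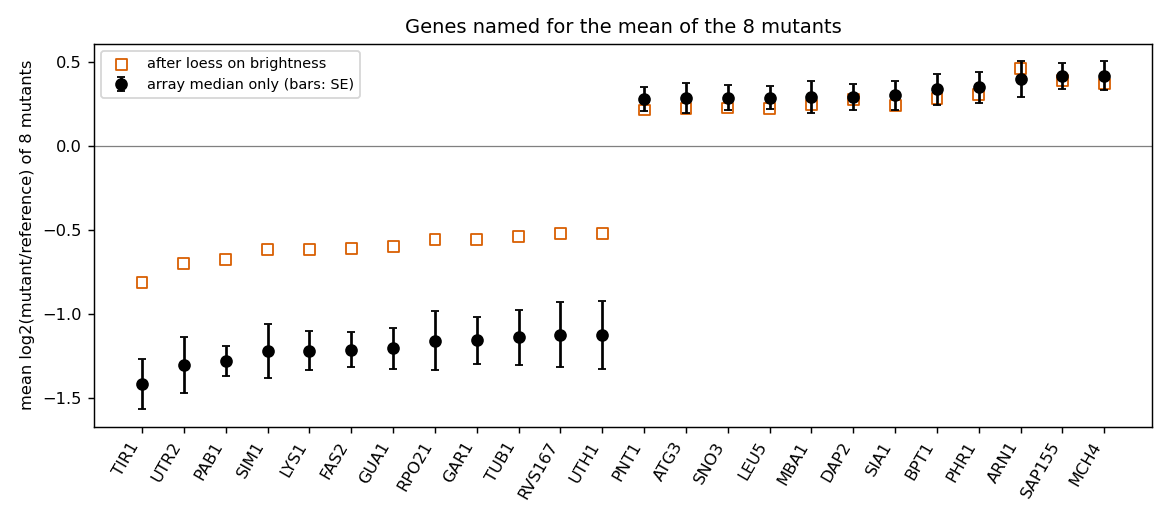
Mean log2 ratio of 8 mutants (y axis, bars are SE) for the 24 genes named for that mean (x axis), with array medians at 0 (black) and after a loess on brightness (orange squares). TIR1 moves from -1.42 to -0.81, and MCH4 from 0.42 to 0.37.

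In all, 540 genes passed in the mean, 85 higher and 455 lower, and 350 of them had 1 sign in all 8 mutants, 35 higher and 315 lower (533 and 200 with the opposite orientation of slide 2, 35 and 158 without PY-231 replicate 1, and 155 and 36 after the loess on brightness). With 1 mean per slide 2 genes were higher and 359 lower. With a replicate block 569 passed. With the opposite orientation of slide 2 there were 782 higher and 505 lower, and without replicate 2 there were 658 higher and 530 lower. The lower genes were bright ones, at a median brightness percentile of 92.9, against 25.5 for the higher genes. That 92.9 is the rank shared by genes at the brightness ceiling, and the cytosolic ribosomal protein and oxidative phosphorylation lists had the same median. After the loess on brightness 194 genes were higher and 112 lower, and with the opposite orientation of slide 2 all 12 of the lowest genes named above turned to 0.709 to 1.257.

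Cytosolic ribosomal protein genes fell in the mean, with a median of -0.71 and 87 of 135 lower over all genes, 126 adjusted over the list alone (adjusted p = 7.45e-40, and adjusted p = 0.811 with an estimated correlation). RPS7B had -1.09 ± 0.12 and RPL2B -1.05 ± 0.12. The direction of the lists in the mean rests on that of slide 2, which is likely but not stated. With the opposite one, list shifts over all contrasts were mostly up (97 up and 14 down). After the loess the list was still down in the mean, at a median of -0.10 (adjusted p = 5.89e-06), but in PG-259 and PG-132 it turned up (adjusted p = 0.909 and 0.049). Its median brightness was at the ceiling, where the loess moves genes together and cannot remove a trend among them. Mitochondrial ribosomal protein genes shifted up with a median of 0.10, and 1 of 57, MRPL16 at 0.27 ± 0.07, passed over all genes (adjusted p = 0.000521, and adjusted p = 0.825 with an estimated correlation). Without replicate 1 that list had an adjusted p of 0.0614. Oxidative phosphorylation genes shifted down with a median of -0.47 and 17 of 31 lower (adjusted p = 0.000216, and adjusted p = 0.813 with an estimated correlation), and turned up after the loess (adjusted p = 0.000982). Hypoxic genes shifted down, with 4 of 16 lower (adjusted p = 0.00903, and adjusted p = 0.811 with an estimated correlation), and also after the loess (adjusted p = 0.00075), with TIR3 at -0.53 ± 0.16 and OLE1, the fatty acid desaturase, at -0.38 ± 0.12.

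Of the lists tied to tolerance of plant hydrolysates, 3 did not pass in the mean. Aldehyde reductases and dehydrogenases had a median of -0.03 over 20 genes (adjusted p = 0.497), drug efflux genes a median of 0.01 over 22 genes (adjusted p = 0.959) and weak acid response genes a median of -0.05 over 14 genes (adjusted p = 0.635). Others shifted down, namely heat shock proteins and chaperones with SSA1 at -0.99 ± 0.16 (list adjusted p = 0.000468, and adjusted p = 0.811 with an estimated correlation), oxidative stress defence with GRX2 at -0.71 ± 0.16 (list adjusted p = 0.0284, and adjusted p = 0.811 with an estimated correlation), general stress genes with PGM2 at -0.65 ± 0.18 (list adjusted p = 0.0273, and adjusted p = 0.819 with an estimated correlation) and ergosterol synthesis with ERG8 at -0.82 ± 0.13 (list adjusted p = 0.00159, and adjusted p = 0.813 with an estimated correlation). None of these 4 passed after the loess on brightness (adjusted p = 0.962, 0.446, 0.465 and 0.871), where the first 2 turned up. Of the 459 list tests, 119 passed with the preset correlation (22 up and 97 down) and 0 with an estimated one, where the smallest unadjusted p was 0.00057, and 20 by fry. With the opposite orientation of slide 2 there were 97 up and 14 down, without replicate 2 there were 42 up and 18 down, and after the loess on brightness 39 up and 40 down.

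Mutants with the same reference can be compared without it. Among the 4 with the DsRed reference, the 10 genes with the smallest p were AAD3, BAR1, MFA2, MSR1, SMA2, RDS1, MRP4, MED6, SAS5 and YCK2, led by AAD3 and BAR1 at an adjusted p of 0.394. Among the 3 with the GFP reference these were SPR1, at an adjusted p of 0.175, INH1, PSP1, YAP1801, PCH2, NPR3, IBA57, AYR1, DAL80 and RPN3. The moderated F test of limma called 0 genes in each, with 226 and 41 at an unadjusted p under 0.05, and 0 genes with a replicate block. On the list means it called 0 of 51 lists in each. The smallest adjusted p was 0.122 with the DsRed reference, for a-cell-specific genes, and 0.999 with the GFP reference. Without M1 replicate 1, 9 genes were called among the mutants with the DsRed reference.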

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

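The tests in this part, the counts of other splits included, were written down only after the results were seen. On each slide the 8 arrays were compared for every chromosome and a few other measures, and an array was singled out when its gap to the nearest other array took most of the range. This happened in 7 of 57 sets of 8 arrays, where chance gives about 1 in 20. The share of the range was 0.879 for chromosome VIII on PG-259 replicate 1, 0.844 on PR-438 replicate 2 and 0.664 on PR-438 replicate 3. It was 0.816 for a-cell minus alpha-cell genes on M1 replicate 2 and 0.725 on M1 replicate 3. For chromosome II on M1 replicate 2 it was 0.529, at a median of -0.06, and for chromosome XVI on PY-231 replicate 2 it was 0.7, at a median of -0.04.

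Chromosome VIII genes were high on PR-438 replicates 2 and 3 and on the array labelled PG-259 replicate 1, but not on PR-438 replicate 1. A trend with brightness is argued against, since after the loess the lowest of the 3 arrays was at 0.401 and the highest other chromosome on any array at 0.12. The fitted shift in PR-438 went from 0.306 ± 0.066 to 0.285 ± 0.067, and this slightly lower estimate at nearly the same SE ended the call (adjusted p = 0.025 to 0.0626). Each of 4 stretches of the chromosome was high on these arrays, the lowest at 0.345 against 0.284 for the highest stretch on the other 21 arrays. An extra copy of the chromosome in the cells may account for this, as a hypothesis, but the size of the shift was not compared with what such a copy would give. An exchange of the labels of PR-438 and PG-259 on slide 1 could explain which arrays show it, but mutants could not be recognised by other genes (0 of 8 on slide 2 were closest to their own array on slide 3), so it cannot be told apart from a difference between cultures.

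Mating-type genes differed on M1 replicates 2 and 3 and not on replicate 1. Poor signal is argued against, with 0.737 for the correlation of a gene's probes on replicate 1 against 0.815 and 0.675, and so is an exchange with one of the 6 other slide 1 arrays with signal, where the highest a-cell minus alpha-cell difference was 0.86 against 7.88 and 9.14 on M1 replicates 2 and 3. On those arrays 10 of 11 mating-type genes differed by over 1 in the direction that an M1 of mating type a against a reference of mating type alpha would give. This may be the case, as a hypothesis. An exchange with PY-231 replicate 1, which carried no signal, or with a sample outside the series stays open.

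Bright genes were low in the mean of the 8 mutants. One dye bias shared by all arrays is argued against, because 4 of the 16 arrays with the mutant in Cy5 fell with brightness as slide 2 did, all of them DsRed arrays on slide 3. A dye bias that differs between arrays may explain much of it, since 112 genes in place of 455 were lower after the loess, but the loess takes out any trend, whatever its cause. The ratio fell with brightness on 14 of 24 arrays, among them all 8 of slide 2, while it rose on 10 of the 16 arrays of slides 1 and 3. The pattern thus rested mainly on slide 2, whose direction is not stated. Lower expression of abundant genes in the mutants stays open as well, so these explanations cannot be told apart.

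The F tests gave 0 genes among the 4 mutants with the DsRed reference and 0 among the 3 with the GFP reference. With 0 genes in the real split, all 100 of the 100 splits of the arrays that were drawn gave at least as many in each whatever the data, so this count says nothing about chance. Of these splits, 9 and 4 called any gene, with 5 and 27 in the highest other split, and what sets those apart was not tested.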

How the results depend on the processing

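The loess on brightness, the removal of the dimmest probes, the removal of single arrays and 1 mean per slide were chosen after seeing the data. The median of a gene's probes and the genes on all 24 arrays left every count within 1.5 times its reported value. PY-231 had 0 genes in every setting but the opposite orientation of slide 2. The GFP comparison kept 0 except with scaling and arrayWeights, and the DsRed comparison kept 0 except without replicate 1 and without M1 replicate 1. Where limma called 0 genes, the count at an unadjusted p under 0.05 lay between 2 and 1267 over all settings. Leaving out replicate 2 leaves 1 dye orientation, so no dye term could be fitted there. The mean of 8 mutants from arrays with the same reference only was not run. Weak signal limits PY-231 replicate 1 in particular. The cause was not tested for the changes below, except where fewer arrays were used.

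In a paired fit with a replicate block, 20 genes were called in PR-438, 8 in PR-338, 34 in PR-164 and 43 in M1. The mean of 8 mutants gave 569 genes, the lists 113 shifts and the chromosomes 1.

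With no dye term there were 0 genes in PR-438, PG-259, PG-132, PR-164 and M1, 2 in PR-338, 236 in the mean of 8 mutants and 70 lists. Without centring there were 0 in PR-438, PR-338, PG-259, PG-353, PG-132 and PR-164, 6 in M1 (4 higher and 2 lower, against 4 and 6) and 2718 in the mean (2629 higher and 89 lower, against 85 and 455 in the main fit). With arrays scaled to the same spread there were 297 in PR-438 (74 higher and 223 lower, against 0 and 12), 115 in PR-338, 0 in PG-259 and PG-132, 37 in PR-164, 3 in M1 (all higher) and 1 among the GFP mutants. With trend and robust settings there were 0 in PR-438, PG-259, PG-132 and PR-164, 1 in PR-338 and 3 in M1. With arrays of the same reference only there were 8 in PR-338, 5 in PG-259, 9 in PG-353, 18 in PG-132, 35 in PR-164, 18 in M1 and 0 chromosomes. With arrayWeights there were 162 in PR-438, 25 in PR-338, 1299 in PG-259, 10 in PG-353, 36 in PG-132, 5 in PR-164, 2 in M1, 1001 in the mean and 1 among the GFP mutants.

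After the loess on brightness there were 0 genes in PR-438, PG-132 and PR-164, 2 in PR-338, 1 in PG-259, 3 in M1, 306 in the mean, 79 lists and 0 chromosomes. Without the dimmest probes there were 30 in PR-438, 0 in PG-353 and 5 in M1. Of the list tests, 0 passed with an estimated correlation and 20 by fry, and 0 chromosomes passed with the chromosome mean. With 1 mean per slide 361 genes passed in the mean of 8 mutants, 2 higher and 359 lower.

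Leaving out a replicate or a single array gave 0 to 54 genes in PR-438, 0 to 8 in PR-338, 0 to 6 in PG-259, 0 to 2 in PG-353, 0 to 63 in PG-132, 0 to 35 in PR-164, 8 to 105 in M1 and 434 to 1188 in the mean of 8 mutants. It gave 0 to 9 genes among the DsRed mutants, 60 to 128 lists and 0 to 1 chromosomes. Without replicate 2, TUB1 and UTH1 in the mean turned to 0.118 and 0.107, and without replicate 3 these were at -1.238 and -1.485.

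The opposite orientation of slide 2 gave 69 genes in PY-231, 58 in PR-438, 1 in PR-338, 154 in PG-259, 0 in PG-353, 446 in PG-132, 289 in PR-164, 472 in M1, 1287 in the mean and 0 chromosomes. Of the 1287, 782 were higher and 505 lower, against 85 and 455, and 97 lists were up and 14 down, against 22 and 97. It turned 37 of 58 named results. In PR-438, ARG1 went to 0.367, GUA1 to 0.605, RPL13A to 0.638, TKL1 to 0.916, PAB1 to 0.831, RPS10B to 0.424 and chromosome VIII to -0.008. In PR-338, SBP1 went to 0.538 and PAB1 to 0.934, and in PG-259 FKS1 to 0.817. In PG-132, PHB1 went to 0.338, SMI1 to 0.482 and ACC1 to 0.932. In PR-164, TIR1 went to 0.826, PAB1 to 0.54, LYS1 to 0.54 and GUA1 to 0.285. In M1, MFA2 went to -0.344, TIR1 to 0.816, FAS2 to 0.456, PAB1 to 0.645, FKS1 to 0.772, STE2 to -0.11 and STE3 to 0.447. In the mean, SIA1 went to -0.233, TIR1 to 0.899, UTR2 to 0.928, PAB1 to 0.888, SIM1 to 1.037, LYS1 to 1.003, FAS2 to 0.952 and GUA1 to 0.78. There RPO21 went to 0.709, GAR1 to 1.091, TUB1 to 1.257, UTH1 to 1.229 and RVS167 to 1.09.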

Other observations

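Amino acid synthesis and central carbon genes were also low in the mean of the 8 mutants. This rests on the direction of slide 2, which is likely but not stated. With the opposite one, 97 list shifts over all contrasts were up and 14 down, against 22 and 97. Of 42 amino acid synthesis genes outside arginine and methionine, 16 were lower, among them ILV5 of branched-chain synthesis at -1.09 ± 0.14 and HIS4 of histidine synthesis at -1.08 ± 0.16 (list adjusted p = 2.33e-05, and adjusted p = 0.811 with an estimated correlation). Of 20 glycolysis and fermentation genes 5 were lower, among them PFK1, a phosphofructokinase subunit, at -0.88 ± 0.15 (list adjusted p = 1.31e-05, and adjusted p = 0.813 with an estimated correlation). Of 10 pentose phosphate genes 3 were lower, with TKL1 at -1.06 ± 0.09 and TAL1, the transaldolase, at -0.99 ± 0.15 (list adjusted p = 0.0237, and adjusted p = 0.811 with an estimated correlation). After the loess on brightness, chosen after seeing the data, the glycolysis list turned up (adjusted p = 0.959) and the other lists were down at an adjusted p of 0.873 and 0.0608.

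AAD3 and RDS1 were low on all arrays of PR-338 and PR-164, and they were low also on replicate 1 of other mutants. In PG-353 AAD3 had -2.60 and RDS1 -2.87 on replicate 1, against -0.34 and -0.54 on replicate 2 and -0.50 and -0.26 on replicate 3. On replicate 1 of PG-259, PG-132 and M1 AAD3 had -1.30, -1.30 and -0.91, and RDS1 had -0.91, -0.55 and -0.64. On replicate 1 of PR-438 and PY-231 AAD3 was at -0.22 and 0.15, and RDS1 was at 0.075 and -0.03. HMRA1, a copy of a mating-type gene on the same chromosome, had -3.93 on PG-353 replicate 1, and 5.35 and 4.16 on M1 replicates 2 and 3. These genes were chosen after their values were seen.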
